A study of Caenorhabditis elegans with 6 samples.

How the data were processed

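Small RNA was sequenced from whole adult males of the nematode Caenorhabditis elegans, 3 libraries from wild type animals and 3 from animals carrying a null allele of prg-1, the gene for the Piwi-class Argonaute PRG-1. Per the labels' protocols, each library came from 20 to 30 males grown at 25 °C and collected 24 h past the mid-L4 stage. RNA was treated with an acid pyrophosphatase before adapter ligation, which lets RNAs with a 5′ triphosphate be cloned, and libraries were made with a kit for small RNA. Per the submitters' processing notes, FastQC 0.12.0, cutadapt 3.7 and the genome build WBcel235 were used. The aligner, its mismatch setting and its rule for reads that fit several places are not given in the sources used here.

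The authors deposited expected counts, in the sense that a read fitting several features was counted by an unstated rule. Per the file headers, the first table counts trimmed reads on 35862 annotated transcripts of 22013 genes (20222 protein-coding genes and 1791 pseudogenes), and the second counts them on 104 bins of 1000000 bases of the genome, each split into sense and antisense reads. Another deposited column beside each count lists the same reads by length and first base, and these lists summed to the count in every row. The deposited values were already whole and not normalized, so rounding changed nothing. Near-identical genes may share or exchange reads under that unstated rule, and values for members of multigene families are uncertain to that extent.

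22G-RNAs, the secondary siRNAs made by RNA-dependent RNA polymerases, were taken as antisense reads of 21 to 23 nt starting with G on protein-coding genes. Each gene was represented by its isoform with the highest mean over the 6 libraries. The richest isoform of each gene within a library held 98.2% to 98.8% of the 22G reads of that library, an upper bound for the isoform used. Reads of 21 nt starting with T (U in the RNA) stood for 21U-RNAs, the piRNAs of this species, because no 21U-RNA is listed singly in the tables used. Any other read of that length and first base was counted with them. Annotated piRNA loci (15363) were counted per bin in the Ensembl annotation of WBcel235, the assembly also named ce11 in the file header.

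Genotypes were compared with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood test after filterByExpr and TMM scaling, with genotype as the only term and a Benjamini-Hochberg (BH) threshold of 0.05. Per-gene levels are CPM, TMM-scaled counts per 1000000 22G reads of the tested genes, given as mean ± SD over 3 libraries. For genes with no read in 1 group, a bound was computed as the mean CPM of the other group over that of 3 counts in the 3 libraries of that group, which was 4.13 CPM in prg-1 null and 7.26 CPM in wild type. Totals were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Intervals for shares are exact binomial with 95% confidence, and intervals and bounds cover counting error only, since reads carry no molecular identifiers. Figures and totals used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

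17 gene lists, the rule for named genes and most alternatives were set before the data were examined. The lists were replication-dependent histones, major sperm proteins, other spermatogenesis genes, oogenesis and eggshell, meiotic prophase, piRNA biogenesis, siRNA amplification and germ granules, sex determination and dosage compensation, reported PRG-1 targets, reported ERGO-1 class targets, cytosolic ribosomal proteins, muscle, intestine, epidermis and neuron markers, ribosomal RNAs and X-linked genes. They came from general knowledge of the field, and names missing from the tables were looked up by sequence name in a RefSeq gene table. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), and with an estimated correlation and fry as alternatives. The text names prg-1, xol-1, bath-45 and fem-1. It also names, among genes past BH 0.05 with at least 10 CPM in the higher group and no overlap between groups, the 8 with the largest log2 fold change and the 4 with the smallest p in each direction. For each list it names up to 2 members with the largest significant rise and 2 with the largest significant fall, or the 2 most abundant members where none passed.

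Alternatives were DESeq2 1.42.0, library-size scaling, other filters on low counts, a replicate block, a 2-fold minimum, summed isoforms, 22-nt reads alone, limma-voom and leaving out each library. Chosen after seeing the data were all antisense reads, scaling to genome-aligned reads without 2 dominant features (on the genes of the main comparison as well), thinning to the smallest library, each of these with the low-count filter run again, keeping pseudogenes in the fit, leaving prg-1 out of the piRNA list, and a piRNA total limited to bins with at least 900 annotated piRNA loci. The 2 dominant features were sense reads on rbd-1 (9.72% to 28.9% of genome-aligned reads) and antisense reads on daf-15 (2.90% to 6.74%), whose origin is not known. In simulated counts for 2879 genes with 200 changed, the edgeR test recovered 6 of 67 genes changed 2-fold, 34 of 67 changed 4-fold and 64 of 66 changed 16-fold, with 9 of 113 calls false. No pair of libraries of 1 genotype agreed within sampling noise, with chi-square per degree of freedom from 3.86 to 8.31. This cannot tell separate cultures from repeat preparations of 1 RNA sample. Libraries were counted as replicates, as labelled. The labels call them replicates without saying whether they came from separate cultures, so p-values measure the spread between these libraries.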

Results

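Small RNAs of adult males were profiled in 3 wild type and 3 prg-1 null libraries, to find how 22G siRNAs on protein-coding genes differ when the piRNA-binding Argonaute PRG-1 is missing. Genome-aligned reads numbered 1226370, 1799846 and 973971 in the wild type libraries and 1133888, 1665708 and 2205341 in the prg-1 null libraries. Antisense 22G reads on protein-coding genes numbered 114763, 309541 and 70387 in wild type and 176078, 292111 and 378138 in prg-1 null, so the third wild type library was the shallowest.

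The targeted gene itself was measured first. Antisense 22G reads on prg-1 (WBGene00004178; WBcel235 chromosome I, 7585324 to 7588367) numbered 143, 441 and 88 in the wild type libraries and 7, 15 and 9 in the prg-1 null libraries. That is 1482 ± 350 CPM against 43.4 ± 13.2 CPM (SD, n = 3 each), a fall of 5.09 ± 0.47 on the log2 scale (SE; edgeR adjusted p = 5.8e-09). Sense reads on prg-1 were few, at 22, 8 and 16 in wild type and 3, 2 and 7 in prg-1 null. These are siRNA and short sense reads, and the part of the gene that the allele removes is not given in the labels, so they do not measure prg-1 mRNA.

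21U-RNAs, the piRNAs that PRG-1 binds and stabilises, come mostly from 2 clusters on chromosome IV. In the 6 bins of 1000000 bases on chromosome IV with at least 900 annotated piRNA loci, which hold 88.7% of all annotated piRNA loci, 21-nt reads starting with T were 9.93-fold lower in prg-1 null. They stood at 1511 ± 562 per 1000000 other genome-aligned reads in wild type and 152.2 ± 20.3 in prg-1 null (SD, n = 3), with p = 0.1 by the exact two-sided permutation test, the smallest it can give. The ratio of wild type to prg-1 null ran from 4.12 to 78.9 over the 6 bins. The bin from 15000001 to 16000000, with 3519 loci, had the highest ratio, at 478 ± 186 against 6.06 ± 3.75 per 1000000 (exact p = 0.1). The last bin, from 17000001 to 17493829 with 502 loci, showed no such difference, with 195 ± 73.3 against 222 ± 179 per 1000000 (exact p = 1). Over the whole genome, 21-nt reads starting with T did not separate the genotypes, at 15196 ± 2791 against 16449 ± 664 per 1000000 (exact permutation p = 0.8). Only 1629 of 14574, 3786 of 28822 and 1006 of 16552 such reads in the wild type libraries lay in the 6 bins. The genome-wide total thus counts mostly reads from outside these bins and is a poor measure of 21U-RNAs. The limit to bins rich in piRNA loci was set after seeing the data.

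**Figure D1:**
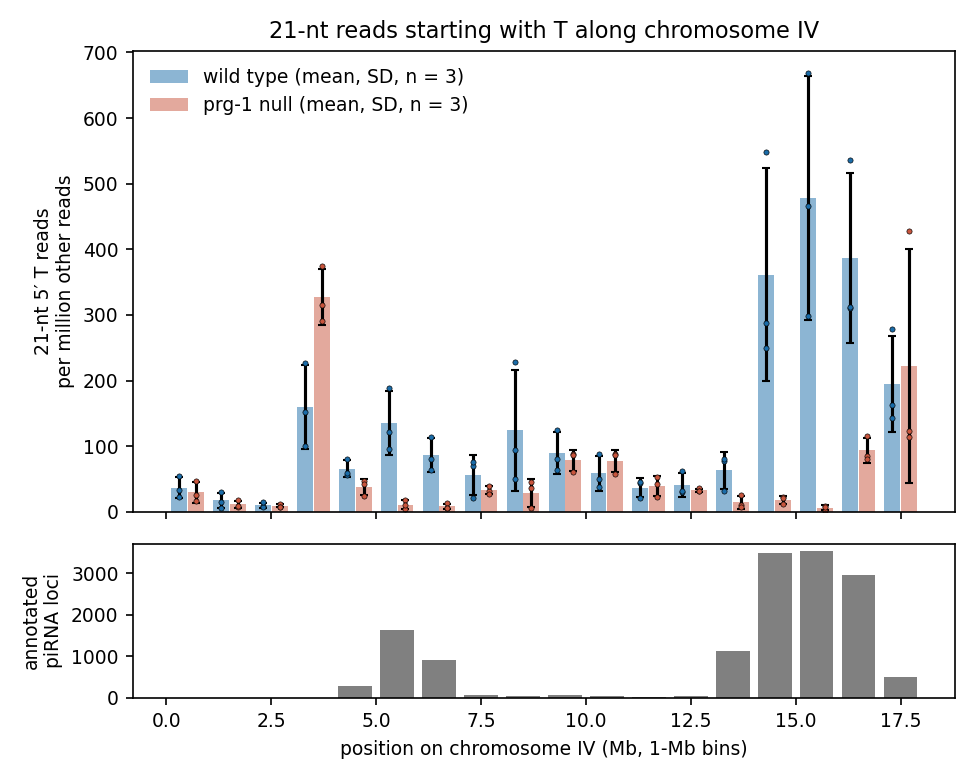
Top, 21-nt reads starting with T per 1000000 other genome-aligned reads in bins of 1000000 bases along chromosome IV (WBcel235), as mean (bar), SD (error bar) and single libraries (points) for 3 wild type and 3 prg-1 null libraries. Bottom, annotated piRNA loci per bin; in the bin starting at 15000001, with 3519 loci, the means were 478 in wild type and 6.06 in prg-1 null.

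The main comparison asked which protein-coding genes carry more or fewer antisense 22G-RNAs in prg-1 null males. Of 2879 genes with enough reads to test, 357 had more 22G-RNA and 938 had less in prg-1 null (edgeR, BH 0.05), and 350 and 936 of these changed at least 2-fold. No 22G read was seen in any prg-1 null library for 209 of the genes called lower, and none in any wild type library for 12 of the genes called higher. Across the tested genes, libraries of 1 genotype correlated at r = 0.76 to 0.93 on log CPM, and libraries of different genotypes at -0.01 to 0.07. A gene could pass the filter through reads in 1 genotype alone, which lowers the correlation between genotypes. These values therefore do not describe all genes. Scaled to genome-aligned reads without the 2 dominant features, which raises the median gene by 0.54 on the log2 scale, the split was 578 higher and 850 lower. When the low-count filter was also run again, it was 590 higher and 693 lower of 2541 genes tested.

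**Figure D2:**
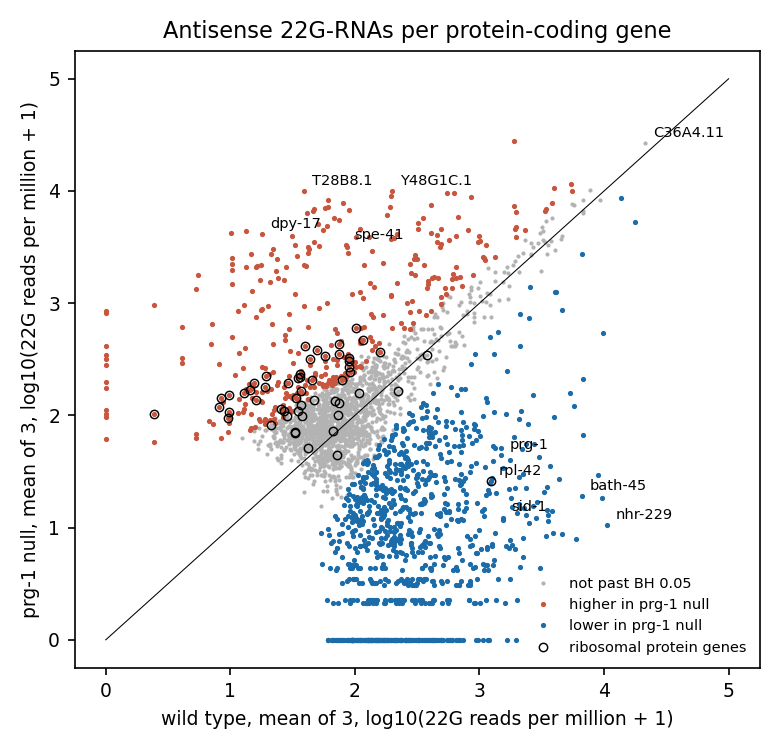
Mean antisense 22G reads per 1000000 in 3 wild type (horizontal axis) and 3 prg-1 null libraries (vertical axis), both as log10(value + 1), for 2879 protein-coding genes, with the line of equality. Colours mark the 357 genes higher and 938 lower in prg-1 null (edgeR, BH 0.05); open circles are 53 ribosomal protein genes, 35 of them higher.

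Among the strongest losses was bath-45 (WBGene00009247; chromosome II, 13123038 to 13124789), a BATH domain gene reported before as a PRG-1 target. Its 22G-RNAs fell 364-fold, from 6619 ± 1274 to 18.2 ± 5.48 CPM (log2 fold change -8.39 ± 0.43, edgeR adjusted p = 2.9e-12). The linker histone-like gene hil-8 (chromosome I, 5463480 to 5469627) fell 316-fold, from 8936 ± 1695 to 28.3 ± 16.2 CPM. C50C3.19 and C01F6.14 fell 595-fold and 563-fold, from 4625 ± 719 to 7.77 ± 4.56 and from 9672 ± 2788 to 17.2 ± 13.7 CPM; each of these 3 genes had an edgeR adjusted p of 3.0e-12. The 8 largest fitted falls were in genes without a 22G read in prg-1 null. K03H9.3 (chromosome II, 6423112 to 6424925), at 1971 ± 604 CPM in wild type, was at least 477-fold lower. The F-box gene fbxc-43, at 1667 ± 136 CPM, was at least 403-fold lower, and lron-11, at 1192 ± 172 CPM, at least 289-fold lower. F44E5.15, F41H10.12, mmab-1, nfm-1 (a merlin-like gene) and Y53F4B.16 were at least 285-fold, 282-fold, 256-fold, 234.97-fold and 228-fold lower.

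Fewer genes gained 22G-RNAs than lost them, by a margin that depended on the scaling and the filter. 22G-RNAs on T28B8.1 (WBGene00012113; chromosome I, 8133891 to 8135037) rose 262-fold, from 37.9 ± 15.6 to 9947 ± 1474 CPM (log2 fold change 8.04 ± 0.41, edgeR adjusted p = 2.9e-12). Talin, tln-1 (chromosome I, 1721592 to 1740670), which links integrins to actin, rose 147-fold, from 45.2 ± 2.77 to 6644 ± 509 CPM. The galectin lec-12 rose 140-fold to 8300 ± 848 CPM, and the annexin nex-2 rose 121-fold to 7235 ± 1248 CPM. C04F12.5 and ZK1098.11 had 4 reads each over the wild type libraries and reached 4430 ± 499 and 4254 ± 470 CPM in prg-1 null, 360-fold and 470-fold higher. The remaining 6 of the 8 largest rises were in genes without a 22G read in wild type. The nucleoporin gene npp-26 and F33H12.1 were at least 116-fold and 112-fold higher, at 843 ± 122 and 816 ± 209 CPM. The predicted chemoreceptor srd-38, sdz-27, F58G6.9 and math-31 were at least 57.03-fold, 47.3-fold, 43.9-fold and 38.5-fold higher. The fitted log2 fold change of C04F12.5 was 8.70, and 8.004 without the second wild type library; that of sdz-27 was 9.03, and 8.44 without the third prg-1 null library.

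Of 53 measured ribosomal protein genes, 35 rose, 1 fell and 17 did not pass over all genes tested, and 37 rose and 1 fell when adjusted over the list alone, with a median log2 fold change of 2.02. Camera called the list higher (adjusted p = 1.8e-06), but not with an estimated correlation (adjusted p = 0.43). The small subunit gene rps-25, with 4 reads over the wild type libraries, rose 19.3-fold between means, from 7.37 ± 6.62 to 142.3 ± 43 CPM (edgeR adjusted p = 4.4e-04). With reads pooled within each genotype and scaled for depth, its ratio was 14.9 (95% counting interval 5.66 to 55.8). rpl-23, with 1 read in wild type, rose to 102 ± 26.3 CPM, a pooled ratio of 40.4 (95% counting interval 7.02 to 1618). The exception was rpl-42, whose 22G-RNAs fell 49.5-fold, from 1228 ± 496 to 24.8 ± 37.3 CPM, mostly from 1 library. Without the second prg-1 null library its log2 fold change was -7.95 in place of -5.50, and without the second wild type library those of rps-25 and rpl-23 were 4.55 and 7.21 in place of 3.86 and 5.10. Summed over all 83 members, ribosomal protein 22G-RNAs stood at 4461 ± 1718 CPM in wild type and 11521 ± 754 CPM in prg-1 null. Sense reads on the same genes stood at 86.5 ± 49 in wild type and 354 ± 50 in prg-1 null per 1000000 genome-aligned reads without the 2 dominant features (exact permutation p = 0.1).

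In the list of piRNA biogenesis genes, 3 of 5 measured members fell and none rose, with the same counts when adjusted over the list alone. Of these, 1 is prg-1, the gene mutated in these animals. The others were tofu-1, whose call was lost with a replicate block (adjusted p = 0.0738), without a filter on low counts (0.0682), with all antisense reads (0.354) and without the first or the third prg-1 null library (0.0591 and 0.121), and parn-1, the ribonuclease that trims piRNA precursors, which fell 22.8-fold from 2084 ± 658 to 91.3 ± 30.3 CPM (edgeR adjusted p = 1.2e-08). In the list of siRNA amplification and germ granule genes, 7 of 33 measured members fell and 1 rose, over all genes and adjusted over the list alone, and 5 fell with a replicate block. Of all 2879 tested genes 938 fell and 357 rose, so both shares in this list were below those over all genes. The double-stranded RNA importer gene sid-1 fell 137-fold, from 1545 ± 65.7 to 11.3 ± 7.61 CPM, and rde-11, needed for exogenous RNA interference, fell 61.9-fold, from 664 ± 151 to 10.7 ± 10.4 CPM. Their log2 fold changes were -6.92 and -5.84, and -7.77 for sid-1 without the third prg-1 null library and -7.04 for rde-11 without the second. The member that rose was Y48G1C.1, by 50.6-fold, from 198 ± 53.4 to 10001 ± 1760 CPM (edgeR adjusted p = 1.5e-11). When scaled to genome-aligned reads, 5 of the 33 fell and 2 rose. Camera called neither list (adjusted p = 0.33 and 0.86). Fry, which asks whether a list moves on balance 1 way without comparing it with other genes, called the piRNA list lower (adjusted p = 0.0097, and 0.0357 for the 4 members other than prg-1); for siRNA amplification the median log2 fold change was 0.03 and the mean -0.54.

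In lists of germline genes few measured members changed, set beside 938 falling and 357 rising of all 2879 tested genes. Tested were 24 of 63 other spermatogenesis genes, 4 of 31 major sperm protein genes and 4 of 36 oogenesis genes. Of meiotic prophase genes 8 of 51 were tested, and of histone genes 4 of 65. The remaining members had too few 22G reads to test and are not covered. Among other spermatogenesis genes 3 of 24 rose and none fell, with 2 rising when adjusted over the list alone (camera adjusted p = 0.11), and 5 of 24 rose when scaled to genome-aligned reads. The sperm channel gene spe-41 rose 39.4-fold, from 83.2 ± 10.4 to 3283 ± 442 CPM, fer-1, a ferlin needed for sperm membrane fusion, also rose, and ssp-31 rose 4.92-fold, from 25.2 ± 21.9 to 124 ± 42.8 CPM (edgeR adjusted p = 0.025). The call on ssp-31 was lost in 5 of the 6 fits that left out a library, all but that without the first prg-1 null library (adjusted p from 0.0121 to 0.0903). Without that library the list itself was called (camera adjusted p = 0.0248 at the preset correlation); with an estimated correlation and all 6 libraries it was not (adjusted p = 0.96). None of 4 measured major sperm protein genes passed in edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05, with log2 fold changes of -0.75 ± 0.54 for msp-19 and 0.27 ± 0.50 for msp-10. None of 4 oogenesis genes passed in these tools, again with 0 at an unadjusted p under 0.05, with 312 ± 196 against 323 ± 51.3 CPM for cey-2 and 136 ± 100 against 174 ± 66.8 CPM for mbk-2, whose log2 fold change of 0.44 was 1.15 without the third wild type library. Of 8 meiotic prophase genes 2 fell and none rose, and 1 fell when scaled to genome-aligned reads. None fell when the filter was also run again (6 tested), with all antisense reads (7), with at least 10 counts (5) or with 22-nt reads alone (3). The pairing centre gene zim-1, at 59.4 ± 26.3 CPM in wild type, was at least 14.4-fold lower, and him-6, a BLM-type helicase, fell 4.29-fold with overlapping libraries (edgeR adjusted p = 0.0136; 0.0662 when scaled to genome-aligned reads). Of 4 measured histone genes his-41 fell, at least 26.3-fold from 109 ± 56.2 CPM, and the other 3 did not pass. The list had a median log2 fold change of 0.19 and a mean of -1.43. No histone gene fell with at least 10 counts (2 tested), with all antisense reads (3) or with genome-aligned scaling and the filter run again (3). With 22-nt reads alone none could be tested.

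In the list of sex determination and dosage compensation, 2 of 14 measured genes fell and 1 rose, and 2 fell when adjusted over the list alone. In the main comparison both shares were below those over all tested genes. When scaled to genome-aligned reads 3 rose and 2 fell, as with all antisense reads. The splicing helicase gene mog-4 fell 10.6-fold, from 228 ± 30.3 to 21.5 ± 2.51 CPM, and mab-3, which controls male-specific differentiation, fell 9.39-fold, from 73 ± 30.2 to 7.77 ± 4.56 CPM (edgeR adjusted p = 0.0038; adjusted p = 0.0592 with a replicate block). The related mog-5 rose 4.29-fold at the edge of the threshold (edgeR adjusted p = 0.048), a call lost in each of the 6 fits that left out a library (adjusted p from 0.0566 to 0.200). The sex determination genes xol-1 and fem-1 had too few 22G reads to test. xol-1 had 18 reads in wild type and 5 in prg-1 null, and fem-1 had 2 and 15. Among reported PRG-1 targets 2 were measured; bath-45 fell, and the other, Y17D7B.4, did not pass, at 6744 ± 678 against 8351 ± 1778 CPM. When scaled to genome-aligned reads, 1 of these 2 was called higher and 1 lower.

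For targets of the ERGO-1 class of siRNAs, the calls depended on the scaling and on the read length. None of 9 measured members passed in the main comparison, with 0 at an unadjusted p under 0.05, nor in DESeq2 or limma-voom. With 22-nt reads alone 1 passed as higher, Y37E11B.2 (log2 fold change 0.73, edgeR adjusted p = 0.0326), with 3 at an unadjusted p under 0.05, and 5 were called higher and none lower when scaled to genome-aligned reads. Relative to other 22G-RNAs the levels were 21181 ± 4538 against 26715 ± 6402 CPM for C36A4.11 and 5523 ± 2273 against 7704 ± 752 CPM for Y37E11B.2. Of the 121 measured X-linked genes 49 fell and 14 rose, against 48 and 22 when scaled to genome-aligned reads and 48 and 7 without a filter on low counts. Camera did not call this list (adjusted p = 0.29), while fry called it lower (adjusted p = 0.0037), and 40.5% of them fell against 31% to 33.9% of genes on each autosome. The difference in shares was not tested. The median log2 fold change of the list was -0.69, and -0.12 when scaled to genome-aligned reads. With the filter also run again it was 0.21. Fry was run on the main scaling only, so its call may depend on that. Of somatic markers, muscle and intestine lists had no gene with enough reads, nor did any ribosomal RNA gene match. The cuticle collagen dpy-17 rose 245-fold, from 16.8 ± 10 to 4117 ± 197 CPM (edgeR adjusted p = 1.3e-11), and the synaptic gene unc-13 stood at 59.1 ± 63.4 against 148 ± 71.7 CPM and did not pass (adjusted p = 0.0433 without the third wild type library, and 0.0324 when scaled to genome-aligned reads).

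**Figure D3:**
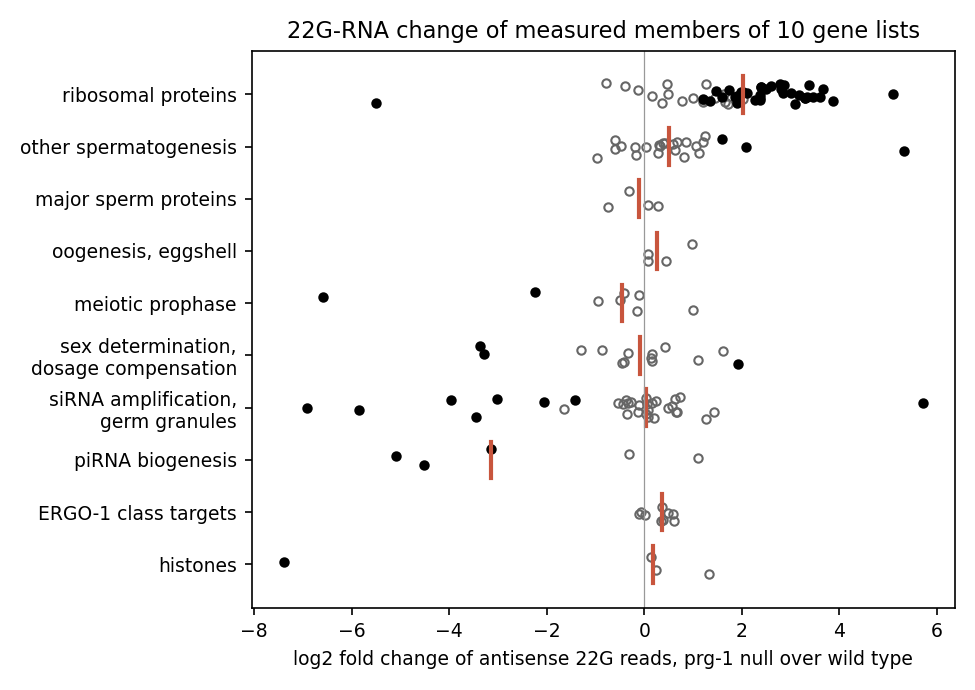
Log2 fold change of antisense 22G reads (prg-1 null over wild type, 3 libraries each) for each measured member of 10 gene lists; filled points passed edgeR at BH 0.05, open points did not, and vertical bars are medians. The ribosomal protein median lies at 2.02, while the median of ERGO-1 class targets lies at 0.36 with no member called; 5 of 9 are called higher when scaled to genome-aligned reads.

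Whether the total of 22G-RNAs on protein-coding genes separated the genotypes depended on the reference. It was 112610 ± 52510 per 1000000 genome-aligned reads in wild type and 167373 ± 10647 in prg-1 null (exact two-sided permutation p = 0.3). The wild type libraries ranged from 72268 to 171982 per 1000000, and the prg-1 null libraries from 155287 to 175367. Per 1000000 transcript-aligned reads it was 196227 ± 96021 in wild type and 271961 ± 31279 in prg-1 null, again with overlapping libraries (exact permutation p = 0.4). Without the reads of rbd-1 and daf-15 in the reference, each prg-1 null library (207246 to 210123) lay above each wild type library (110641 to 196805). The ratio was then 1.49, with an exact permutation p = 0.1, the smallest possible.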

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

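Except for the count of gene lists over other groupings of the libraries, the tests here were chosen or revised after results were seen. The revisions put the scaling and thinning tests on the genes of the main comparison, stopped counting a gene as its own family member, and set antisense reads on ribosomal protein genes against sense reads. Pseudogenes and 26-nt reads were outside the main comparison. Of 173 pseudogenes tested, 81 had less antisense 22G-RNA in prg-1 null and 26 had more (edgeR, BH 0.05), the latter being what drew attention. Examples here were chosen after their values were seen. 22G-RNAs on the pseudogene Y17D7C.3 fell 686-fold, from 13919 ± 1818 to 20.3 ± 9.33 CPM (SD, n = 3), and those on cars-2 fell 408-fold, from 9170 ± 1465 to 22.5 ± 22.8 CPM. hsf-2, listed as a pseudogene, had 3 reads over the wild type libraries and 1022 in prg-1 null. Antisense 26-nt reads starting with G, the 26G-RNAs, were higher in prg-1 null on 11 of 633 genes tested and lower on 3 (edgeR, BH 0.05). Both directions together, DESeq2 called 16 genes and limma-voom 22.

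Ribosomal protein genes drew attention because their sense reads, which the main comparison does not use, were 4.09-fold higher in prg-1 null, and 35 of 53 measured members had more antisense 22G-RNA. Breakdown of their mRNA read on the wrong strand was tested on reads of 21 to 23 nt. In prg-1 null at least 81% (exact 95% interval 79.3% to 82.7%) of antisense reads started with G. Of sense reads 58.2% to 70.9% did, with intervals apart in each of 3 prg-1 null libraries. At least 26.7 antisense reads were seen per sense read at that length (8.72 over all lengths). This argues against breakdown as the main source of these antisense reads. Wild type values were similar, with 85.1%, 87.2% and 87.6% of antisense reads starting with G. Antisense reads per sense read were 22.2, 36.8 and 67.3 there, so the test does not decide on the gain. Losses elsewhere that push these genes up through scaling are argued against by a median log2 fold change of 2.597 when scaled to genome-aligned reads, where the median gene moved up by 0.54, against 2.02 in the main result. After thinning, the median on the same 53 genes was 1.72. Fold changes are already scaled for depth, so this median had little room to move and does not decide on depth. Of 17 members that could be tested after thinning, 13 were higher and 1 lower. A change in siRNA targeting of ribosomal protein genes in prg-1 null males may remain as a hypothesis, and breakdown stays open for the gain. Reads shared with other genes were not tested, and the 4.09-fold higher sense reads and their own preference for G were not explained.

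The losses from 938 genes were weighed against 3 technical explanations. Depth was predicted to bring their median log2 fold change toward 0 after thinning, and it was -5.21 against -5.28 before. Fold changes are already scaled for depth, so this median too had little room to move and does not decide on depth. After thinning, 475 of the 938 stayed called lower (50.6%), with 1021 genes tested in all. Scaling is argued against because 90.6% of them stayed called lower when scaled to genome-aligned reads, and 73.6% did with the low-count filter run again. Reads moving to near-identical genes would leave a gaining member of the same symbol family more often beside lost genes, and the odds ratio was 0.69 (95% interval 0.52 to 0.92; 81 of 440 lost genes with a family symbol had such a member). Without ribosomal protein genes it was 0.85 (0.63 to 1.13), an interval that includes 1, and genes without a family symbol were not covered. Families were formed by symbol alone, unc, let and lin among them, and likeness of sequence was not measured. Exchange of reads therefore stays open beside loss of PRG-1.

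Splits of the 6 libraries into 3 and 3 were too few, at 10, for a share under 0.05. The real grouping called 1295 genes and the highest of the other splits called 0, so 1 split of 10 reached the real count. For gene lists under camera, the real grouping called 1 and the highest other called 4, and 10 of 10 splits called at least as many as the real one.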

How the results depend on the processing

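The settings with all antisense reads, genome-aligned reads, thinning, pseudogenes, the piRNA list without prg-1 and bins rich in piRNA loci were chosen after seeing the data. Direction and side of the threshold held for most named genes. Many of these were picked from the same data for large or significant changes, so their stability does not describe that of other genes. Over 48 named genes and 876 alternative fits, 838 kept both, 21 lost the call, 8 gained one and 9 changed sign, all of these in genes not called. The counts of higher and lower genes stayed within 1.5 times of 357 and 938 except in 3 settings: 578 genes were higher with scaling to genome-aligned reads without the 2 dominant features, 590 when the low-count filter was also run again, and 487 were lower after thinning to the smallest library, where 1021 genes were tested. Leaving out 1 library gave 288 to 401 higher and 785 to 1204 lower. With a replicate block 306 were higher and 890 lower; same-numbered libraries correlated at -0.04, 0.05 and 0.01 in their deviations, so the numbers gave no pairing. The number of called lists was 0 with an estimated correlation, 3 with fry and 1 to 2 without a library, against 1; the cause was not tested. With an estimated correlation of 0.07 in place of 0.01, which leaves fold changes as they are, ribosomal proteins were not called (median 2.02, adjusted p = 0.43); they were called in the other fits (1.94 to 2.51 without a library). Fry added the X-linked and piRNA lists.

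The log2 ratio of 21-nt reads starting with T was 0.11 over the genome and -3.31 in bins with at least 900 piRNA loci. In the wild type libraries those bins held only 1629 of 14574, 3786 of 28822 and 1006 of 16552 such reads, so the genome-wide ratio mostly reflects reads from outside them. The genome-wide log2 ratio ranged from -0.029 (without the first wild type library) to 0.22 with a library left out. That of the 22G total ranged from 0.33 to 1.01 around 0.57, the highest without the second wild type library. Uncalled genes changed sign as follows, for causes not tested: msp-10 (-0.050 with 22-nt reads, -0.50 with all antisense reads), mbk-2 (-0.14 with 22-nt reads), cey-2 (-0.065 with DESeq2, -0.12 with at least 10 counts, -0.29 to 0.53 without a library) and C36A4.11 (-0.034 to 0.45 without a library). Medians of uncalled lists also did. Under genome scaling they were 0.49 for sex determination, 0.37 for major sperm proteins and 0.088 for meiotic prophase, and with the filter run again 0.71, 0.37 and 0.39, with 0.21 for X-linked genes; with a replicate block 0.023 for sex determination and -0.064 for siRNA amplification, which was -0.023 without TMM and -0.18 after thinning. Without a library they ran from -3.02 to -0.35 for histones, -0.33 to 0.24 for siRNA amplification, -0.49 to 0.30 for sex determination, -0.60 to 0.10 for meiotic prophase and -0.42 to 0.38 for major sperm proteins. Scaling to miRNA counts was not run, as no miRNA is listed in the tables used, and a pseudocount did not apply to counts. Depth sets the bound for genes with no read (4.13 CPM in prg-1 null, 7.26 in wild type). In simulated counts for 2879 genes, 6 of 67 changes of 2-fold were called; depth was not varied there.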

Other observations

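Gene families were tested after the main result was seen, by Fisher's exact test over 42 families sharing a symbol and with at least 5 tested members, in both directions (84 tests, BH). Of 13 measured bath genes, which encode BATH domain proteins, 12 lost 22G-RNAs and none gained (odds ratio 25.1, adjusted p = 3.5e-04). Beside bath-45, these included bath-20, which fell from 3027 ± 344 to 41.7 ± 10.3 CPM (SD, n = 3). Of 21 F-box genes of the fbxa family, 14 fell and 1 rose (odds ratio 4.18, adjusted p = 0.019), with fbxa-218 going from 2341 ± 428 to 21.5 ± 15.8 CPM. Of 14 nuclear hormone receptor genes 10 fell and 1 rose (odds ratio 5.21, adjusted p = 0.039). With at least 10 counts 4 of 8 fell, with 22-nt reads alone 5 of 8 and after thinning 3 of 5, with 1 rising each time. 22G-RNAs on nhr-88 dropped from 9886 ± 2565 to 540 ± 201 CPM, while nhr-15 rose from 1007 ± 214 to 3618 ± 579 CPM. All 6 measured enu genes fell (adjusted p = 0.019), and 5 did with genome-aligned scaling, with a replicate block or without a filter on low counts. Collagen genes went the other way, with 7 of 12 rising and 3 falling (odds ratio 10.1, adjusted p = 0.0041). Among them col-111 rose from 207 ± 92.3 to 3840 ± 467 CPM, and col-60 fell from 171 ± 95.9 to 1.11 ± 1.93 CPM. The medians of these families kept their sign under DESeq2, library-size and genome-aligned scaling. With the latter 1 bath gene and 2 fbxa genes were called higher, and 6 of 7 collagen genes rose and none fell when the filter was also run again. Examples were chosen after their values were seen. Members of these families can share reads, so values for single members are uncertain. Fisher's test takes members as independent, so its p-values for these families can be too small.

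The caspase-like gene csp-2 changed in opposite directions in 2 classes of siRNA. Its 22G-RNAs fell 32.1-fold (log2 fold change -5.001 ± 0.36, edgeR adjusted p = 1.1e-10), from 3101 reads in wild type to 154 in prg-1 null. Its antisense 26-nt reads starting with G rose from 5 to 172 (log2 fold change 5.21 ± 0.67, edgeR adjusted p = 1.5e-06). It was chosen after its values were seen, as the gene with the smallest p among 26G-RNAs. Of 377 genes tested in both classes, log2 fold changes correlated across genes at a Spearman rho of -0.03, and genes are not independent replicates. Over all protein-coding genes there were 17.5 ± 10.1 26G reads per 100 22G reads in wild type and 9.61 ± 2.18 in prg-1 null (exact permutation p = 0.3).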
